A study of Homo sapiens with 2 samples.

How the data were processed

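RNA was extracted with Trizol from 1 culture of HepG2 cells per condition, per the labels' protocols, and sequenced on an Ion Proton instrument, per the series' design text. The authors deposited 1 table of RPKM values with a column for each library and none left unused, which names genes by symbol. Per the submitters' processing notes, Bowtie and the human build GRCh37 were used. The version, the annotation, the read counter, the filters and whether strand was used are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The control column carries the code in the control sample's title. The DEHP column is named S01, with the digit 0, where the title has SO1, with a letter, and was matched on that likeness, since no other title has such a code. The 0.25 nM dose stands in the sample title alone.

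RPKM values with full precision keep the whole reads behind them. The reads, gene model lengths and scaling totals were worked back as the smallest whole numbers that give the deposited values, and 41409 of 41440 positive values (99.93%) came out whole with gene models of up to 50000 nt and a relative tolerance of 1e-13. With each total off by 1, 0% did. The recovered lengths had a median ratio of 0.994 to the longest GENCODE release 29 transcript over 7257 genes. The smallest whole reads summed to 91.8% of the total in both libraries. The rest can be true reads that are multiples of them, or reads outside the listed features. In simulated libraries 85.4% of features had their exact reads, and 100% had the exact reads or a whole divisor of them. Multiples are therefore likely part of the rest, but how large a part cannot be told here. A gene's true reads cannot be fewer than its smallest whole reads, so counting error is, if anything, given as too large. Counting intervals are exact conditional binomial (Clopper-Pearson) 95% intervals on the fold. Sequencing reads without molecular identifiers are not independent molecules, so they cover counting error only. An exact binomial comparison of the recovered reads, with Benjamini-Hochberg adjustment over 12991 features, compares these libraries and not the conditions. It gave 1007 features higher and 755 lower at an adjusted p under 0.05.

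Features with a mean RPKM of at least 1 entered, and log2((DEHP + 1)/(control + 1)) was computed on RPKM as deposited. Before the data were examined, 51 gene lists, the size thresholds, the alternatives and the rule for named genes were fixed. The lists held 1312 entries, 1311 of them in the file. A list stood apart where its median was under percentile 2 or above percentile 98 of 10000 random lists matched in 20 bins of mean RPKM, as a description of these libraries, and list members were called at 1.5-fold. The named genes are the 14 highest and the 14 lowest log2 ratios among features with a mean RPKM of at least 5, up to 4 members per list with the largest ratio, for lists with no member 1.5-fold apart also up to 2 of the most abundant, and ALB, AFP, PPARA, HNF4A, ACTB and GAPDH. Some genes that the rule takes are not reported here. Other genes named here were chosen after their values were seen. They are FTH1, AKR1C3, AKR1C4, GSTA4, SLC30A1, SLC30A10, SLC39A4, SLC39A10, SLC39A14, MT1A, RPS13, SNHG5, GAS5, MALAT1, NEAT1, S100A9, DDTL, GGTLC1, CPA1, BOLA2B, SULT1A4, BOLA2, EIF3C, EIF3CL, AKR1E2, SLC6A12, C9orf116, HEY1, LCN15, NDUFA3 and TNNI2, as were the family sums. Symbols were matched to RefSeq on GRCh38.p14 for biotype and chromosome (95.8% of features); no coordinates were used. The share of a gene's 32-mers, taken every 10 bases from the transcript with the longest coding sequence in GENCODE release 29, that occur in another gene served as a measure of sequence copies.

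Alternatives changed the pseudocount, the filter, the scaling, the fold threshold and the matching. Restricting to protein-coding genes and to genes with at most 10% of shared 32-mers was added after seeing the data. The steps were tested on simulated data drawn from the control and DEHP libraries' 12991 features. The scaling totals of simulated libraries were recovered exactly, and 85.4% of features had their exact reads. Of 100 genes changed 3-fold, 97 passed the 2-fold rule, and of 100 changed 1.5-fold 0 did. The exact binomial comparison called 99 and 89 of them, and 4 unchanged features. Of 100 unchanged lists of 25 genes, 4 stood apart, and 40 of 40 lists raised by 0.20 on the log2 scale did. The unchanged lists were random draws set against random draws, so a share near 4% was fixed by the cutoffs. How often lists of genes that move together stand apart was not tested. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.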

Results

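RNA was sequenced from HepG2, a human liver cancer cell line that keeps many functions of hepatocytes. One culture had been kept for 3 months with 0.25 nM di(2-ethylhexyl) phthalate (DEHP), a plasticizer, and the other for the same time with control solvent. Each condition had 1 library, so the difference between them has no replicate check, and no test across samples, SD or SE is given. The values are RPKM (reads scaled to the length of the gene model and to the library's total) for 40205 features, of which 17870 were at 0 in both libraries. The scaling totals worked back from the values were 14964680 reads for the control library and 14130990 reads for the DEHP library. A mean RPKM of at least 1 was reached by 12991 features, 10396 of them protein-coding, and these were compared. Folds are ratios of RPKM, DEHP over control, and the range beside a fold is its exact 95% counting interval, which covers counting error only. Log2 ratios were taken after adding 1 to each RPKM, which understates the difference of low genes. The 1.5-fold and 2-fold thresholds were applied to these log2 ratios, so a low gene can have an RPKM fold past 1.5 without passing.

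The libraries of DEHP-exposed and control cells were close to each other, and few protein-coding genes were far apart. The list of the NRF2 stress response, with the aldo-keto reductases AKR1B10, AKR1C1 and AKR1C2, and the list of metallothioneins and zinc transport had higher RPKM in the DEHP library. The metallothionein and zinc transport list did not stand apart among its 7 members with little shared sequence (median 0.09, percentile 86.45). Of these only MT1F is a metallothionein. Summed RPKM was about 1.5-fold higher for the metallothioneins, the AKR1C genes and the GSTA glutathione transferases, families chosen after the values were seen, though not in every member. Ribosomal protein genes and genes of the hypoxia response had lower RPKM, as had the list of nuclear and small non-coding RNAs (median log2 ratio -0.18, percentile 0.03). That list was fixed as a sign of RNA quality, but 4 of its 14 measured members lay above 0, and RNA quality was not tested. Among the 5 ribosomal protein genes with little shared sequence the median was -0.14, and these few did not stand apart (percentile 7.81). Of the 10396 protein-coding genes, 99.02% lay within 1.5-fold, and the median log2 ratio of all 12991 features was 0.03. Pearson's r of log2(RPKM + 1) across these features, which are not independent replicates, was 0.987. At least 2-fold higher in the DEHP library were 86 features and at least 2-fold lower 92, of which 5 and 4 were protein-coding. Libraries simulated with counting error alone gave a median of 47 higher and 47.5 lower, and for protein-coding genes of 2 higher and 2.5 lower. The simulated reads followed the smallest whole reads, which can be fewer than the true reads, so these numbers can be too high. Counting error can give part of the observed counts, and how large a part is uncertain.

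**Figure D1:**
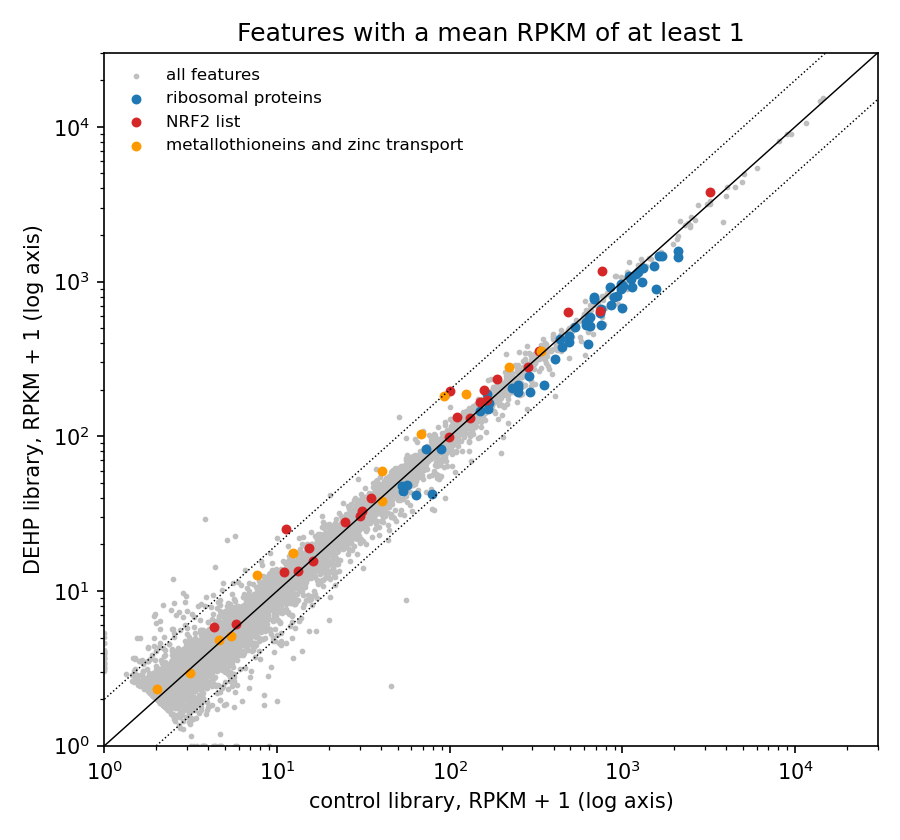
RPKM + 1 of each feature in the control library (x axis) and the DEHP library (y axis), both on log axes, for the 12991 features with a mean RPKM of at least 1, with a solid line at equal values and dotted lines at 2-fold differences. MT1G (91.5 against 181) lies above the line, and most of the 56 ribosomal proteins lie below it.

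The NRF2 list, genes of the oxidative stress and detoxification response, was higher in the DEHP library. Its 25 measured genes had a median log2 ratio of 0.18, at percentile 100 of 10000 random lists of the same size and mean RPKM, and 21 of the 25 lay above 0. At least 1.5-fold higher were 3 members and none was 1.5-fold lower. AKR1B10, an aldo-keto reductase that reduces reactive aldehydes, stood at RPKM 10.3 in the control and 24 in the DEHP library, a fold of 2.33 (1.88 to 2.91). AKR1C2 was at 98.6 and 195 (fold 1.97, 1.91 to 2.04), and AKR1C1, which also reduces steroids, at 765 and 1168 (fold 1.53, 1.5 to 1.56). GCLM, a subunit of the enzyme that starts glutathione synthesis, was at 3.3 and 4.88, with a fold of 1.48 (1.09 to 2.01). These AKR1 genes share 34% to 63% of their 32-mers with another gene, so the division of reads among them is uncertain. AKR1C1 to AKR1C4 summed to 1015 in the control and 1531 in the DEHP library, a difference carried by AKR1C1 and AKR1C2, since AKR1C3 and AKR1C4 had folds of 1.11 (1.06 to 1.17) and 1.03 (0.714 to 1.47). FTH1, the ferritin heavy chain, went against the list with a fold of 0.872 (0.851 to 0.894). It shares 73.8% of its 32-mers with another gene, so its fold is uncertain too.

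The list of metallothioneins, small proteins that bind zinc and other metals, and of genes of zinc transport gave the highest list median, 0.34 (percentile 100). It held 13 measured genes, of which 7 are metallothioneins, and 4 members were at least 1.5-fold higher, all of them metallothioneins. MT1G was at RPKM 91.5 in the control and 181 in the DEHP library, a fold of 1.98 (1.78 to 2.2). MT1M had a fold of 1.76 (1.19 to 2.62), MT1F of 1.53 (1.35 to 1.73) and MT1E of 1.52 (1.41 to 1.63). Among the zinc transporters SLC30A1 had a fold of 1.46 (1.27 to 1.68), while SLC39A4 (0.935), SLC39A10 (0.914), SLC39A14 (1.07) and SLC30A10 (1.07) lay near 1. The 10 metallothionein genes of the file summed to 551 and 823. MT1A had a fold of 0.937 (0.511 to 1.71), an interval that includes 1. Most metallothionein genes are similar in sequence, so the division of reads among them is uncertain. With only the 7 members that share at most 10% of their 32-mers with another gene the list did not stand apart (median 0.09, percentile 86.45), and of these only MT1F is a metallothionein. With only features of a mean RPKM of at least 5 the median was 0.55 over 9 genes.

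Among genes of xenobiotic metabolism driven by PXR, CAR and AhR, 2 of 18 measured members were at least 1.5-fold higher and none passed 1.5-fold lower, and the list as a whole did not stand apart (median 0.07, percentile 86.02). With only features of a mean RPKM of at least 5 it did, with a median of 0.12 over 10 genes (percentile 98.38). GSTA2, a glutathione transferase, was at RPKM 1.43 in the control and 6.54 in the DEHP library, with a fold of 4.58 (3.01 to 7.17). GSTA1 was at 12.5 and 20.9 (fold 1.68, 1.42 to 1.98). GSTA1 and GSTA2 share 48.5% and 29.5% of their 32-mers with another gene, so the division of reads between them is uncertain. GSTA4, the third measured gene of that family, had a fold of 0.859 (0.643 to 1.14). UGT2B4, a glucuronosyltransferase, had a fold of 0.587 (0.422 to 0.81). CYP1A1, the classical target of the aryl hydrocarbon receptor, was low in both libraries, at 2.58 and 3.72 (fold 1.44, 1.11 to 1.87). Phthalates activate PPARα in rodent liver, and the 24 measured PPARα targets and fatty acid oxidation genes did not stand apart (median 0.07, percentile 90.39). None of the 24 was 1.5-fold apart. TXNIP, with a fold of 0.69 (0.621 to 0.767), lay farthest from 0, and PLIN2 and FABP1 had folds of 0.873 and 0.938. PPARA itself was at RPKM 6.44 and 6.64, a fold of 1.03 (0.942 to 1.13). Peroxisome biogenesis genes (median 0.04, percentile 61.37), nuclear receptors (0.01, 31.29) and genes of carboxylesterases, lipases and aldehyde oxidation (-0.02, 15.47) did not stand apart either.

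Genes of cholesterol biosynthesis were slightly higher in the DEHP library, 22 of 24 lying above 0 with a median log2 ratio of 0.15 (percentile 99.99). None was 1.5-fold apart. MVK, which phosphorylates mevalonate, was at RPKM 25.2 and 32.7 (fold 1.3, 1.18 to 1.43), and HMGCS1 at 23.3 and 27.4 (fold 1.18, 1.08 to 1.29). Other metabolic lists did not stand apart: fatty acid and triglyceride synthesis had a median of 0.08 (percentile 93.37), bile acid synthesis and transport 0.10 (92.02), apolipoproteins and lipoprotein handling 0.03 (66.11), gluconeogenesis and glycogen 0.03 (55.80). Glycolysis lay just inside the range of random lists (and outside it under 6 alternatives, at percentiles of 0.61 to 1.91), with a median of -0.07 (percentile 2.52) and 1 member 1.5-fold lower, PGAM1 (46 against 28.9), which shares 48.9% of its 32-mers with other genes.

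Genes of the hypoxia response were lower, with a median log2 ratio of -0.09 (percentile 0.23) and only 4 of 22 measured members above 0, none passing 1.5-fold on the log2 scale. LOX, which crosslinks collagen, was at RPKM 16.2 in the control and 10.6 in the DEHP library (fold 0.651, 0.594 to 0.713). IGFBP1, a secreted binder of insulin-like growth factors, was at 674 and 459 (fold 0.681, 0.664 to 0.697). CA9 and PFKFB4 had folds of 0.722 (0.577 to 0.901) and 0.737 (0.671 to 0.808), while the glucose transporter SLC2A1 had a fold of 1.11 (1.08 to 1.15).

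Ribosomal protein genes were lower in the DEHP library, with a median log2 ratio of -0.18 over 56 measured genes (percentile 0.00) and only 5 members above 0. At least 1.5-fold lower were 6 members and none was as much higher. RPS19 was at RPKM 1567 in the control and 898 in the DEHP library, a fold of 0.573 (0.56 to 0.587). RPL37 was at 351 and 214 (fold 0.61, 0.589 to 0.633), RPS27 at 77.7 and 41.3 (fold 0.532, 0.448 to 0.631) and RPS15 at 630 and 393. RPS13 went the other way, at 680 and 798. Nearly all ribosomal protein genes have processed pseudogenes that share their reads, and only 5 members share at most 10% of their 32-mers, with a median of -0.14 that did not stand apart (percentile 7.81). The 1108 pseudogenes of these ribosomal protein genes summed to RPKM 25781 in the control and 22122 in the DEHP library. The list of nuclear and small non-coding RNAs, fixed as a sign of RNA quality, was lower in the same library (median -0.18, percentile 0.03). Its members did not move together, and 4 of 14 lay above 0. SNHG6, which hosts a snoRNA, had a fold of 0.602 and RN7SL1 of 1.38 (0.982 to 1.96). Whether RNA quality differed was not tested.

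The other 4 lists that stood apart were those of the proteasome, DNA replication, chromatin regulators and coagulation. The proteasome list was higher (median 0.11 over 30 genes, percentile 99.96), with PSMA4 at a fold of 1.27 (1.16 to 1.39) and PSMA7 at 1.2 (1.13 to 1.27). DNA replication genes had a median of 0.09 over 37 genes (percentile 98.98), with ORC6 at 1.4 (1.16 to 1.68) and ORC1 at 0.787 (0.676 to 0.916). DNA methylation and chromatin regulators had a median of 0.11 (percentile 98.34), with KDM6A at 1.25 (1.07 to 1.45). Coagulation and complement factors were lower, with a median of -0.06 over 28 genes (percentile 1.74). FGA, a fibrinogen chain, was at 128 and 90.6 (fold 0.708, 0.682 to 0.735), while C1S was at 4.18 and 7.3 (fold 1.74, 1.44 to 2.12). The calls for DNA replication and for chromatin regulators ended when only features with a mean RPKM of at least 5 were kept (percentiles 95.49 and 97.58), that for chromatin regulators also with a pseudocount of 5 (96.17) and with members sharing at most 10% of their 32-mers (96.14), and that for coagulation factors ended without a filter (2.54). With each library rescaled to a common sum the median of coagulation factors was -0.04 (percentile 1.67). In all 10 of 47 lists with at least 5 measured genes stood apart, where 1.9 are expected for lists of genes drawn independently. Genes of a fixed list can move together and some lists share members. With 1 library per condition the number expected for such lists is unknown, so 10 is not a test against chance.

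**Figure D2:**
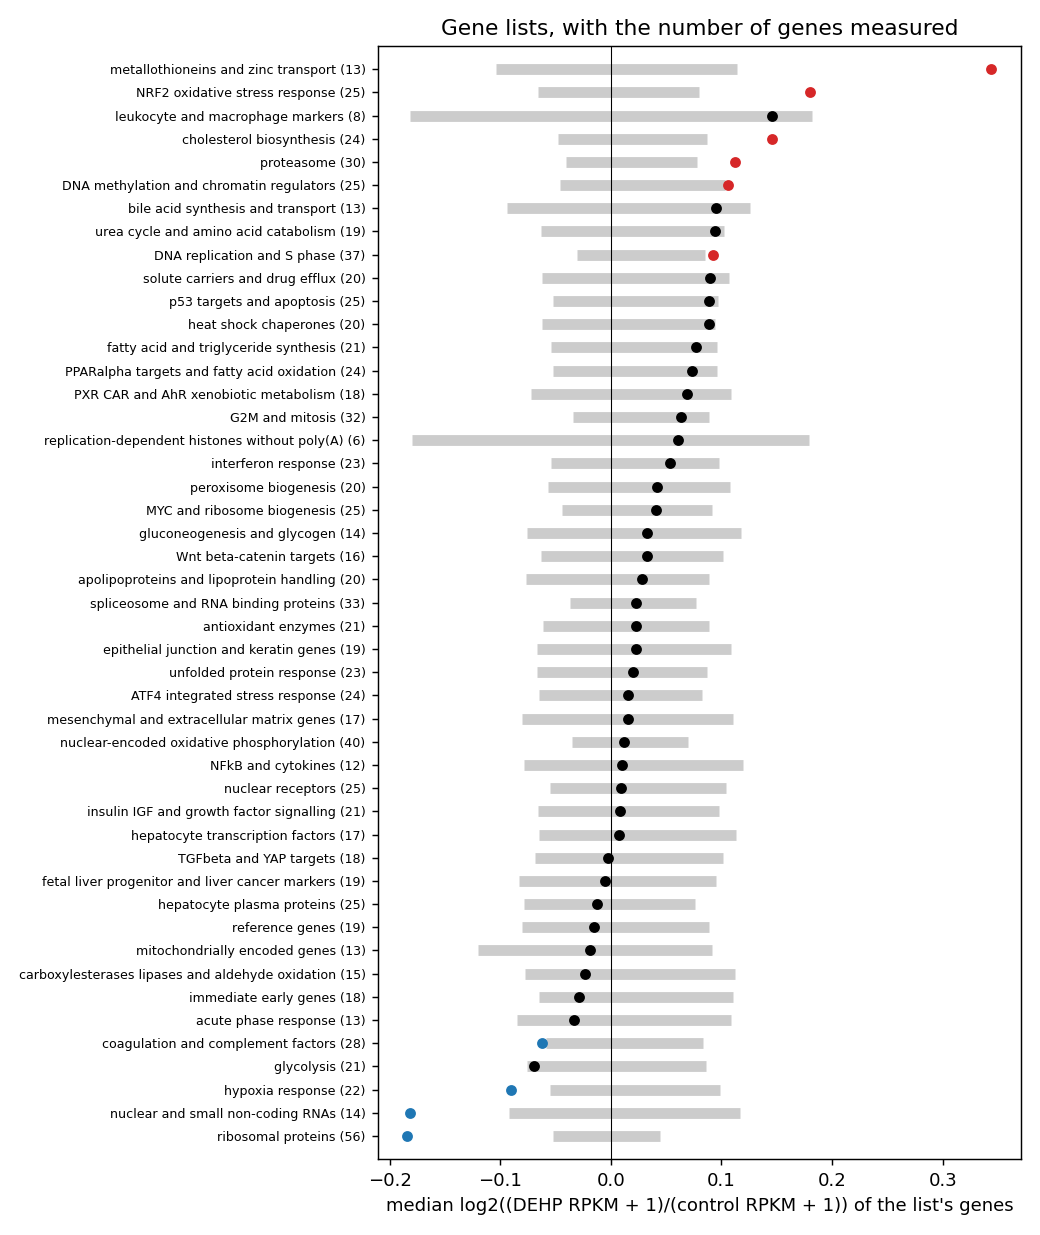
Median log2 ratio of RPKM + 1, DEHP over control, of the 47 gene lists with at least 5 measured genes (points), with the number of genes measured in parentheses and gray bars that span percentiles 2 to 98 of 10000 random lists matched on mean RPKM. Red points mark the 6 lists above and blue points the 4 lists below these bars.

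**Figure D3:**
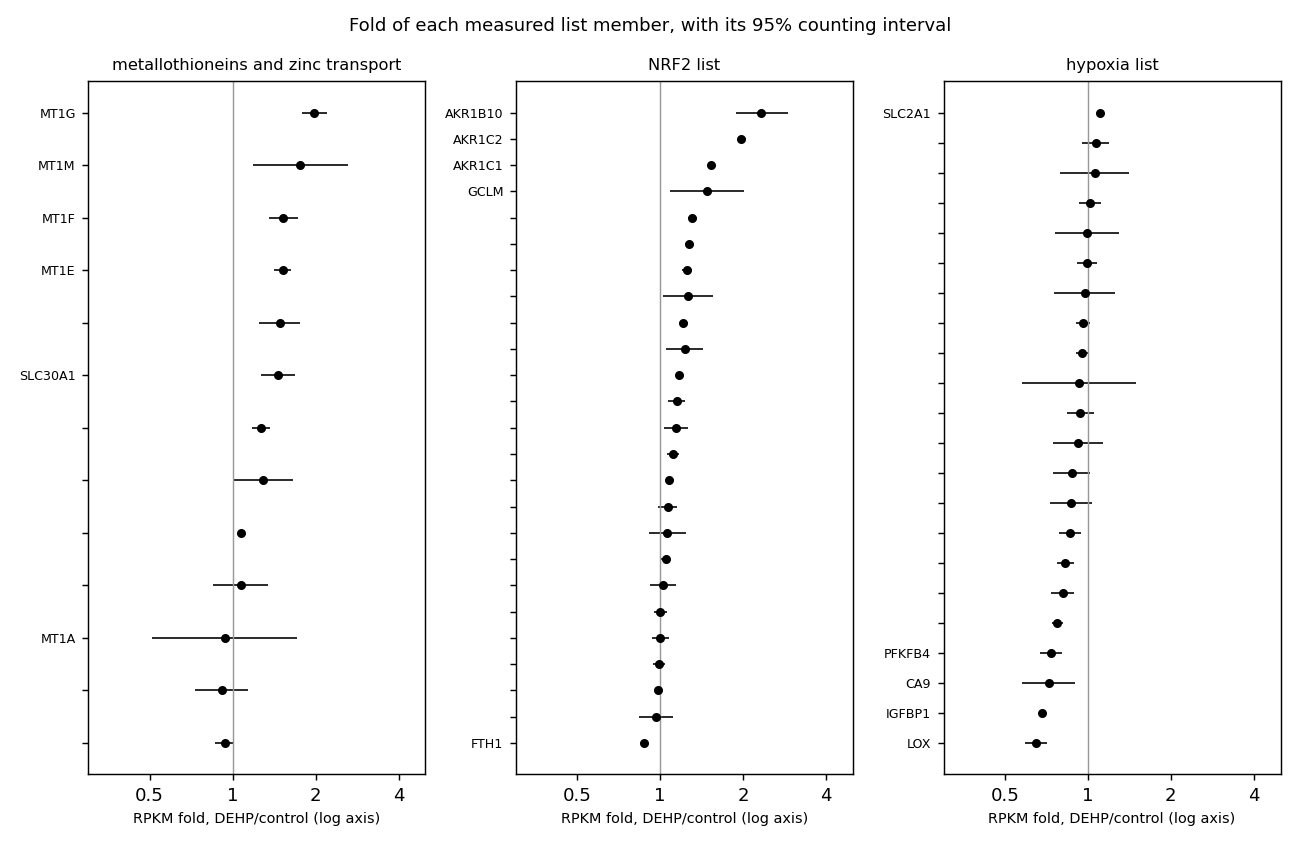
RPKM fold, DEHP over control, on a log axis, of every measured member of 3 lists (metallothioneins and zinc transport, NRF2 and hypoxia), with 95% counting intervals as bars. Labels mark some of the genes named in the text. AKR1B10 at 2.33 is the highest member of the NRF2 list, and LOX at 0.651 the lowest of the hypoxia list.

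Genes of hepatocyte identity did not stand apart in 5 lists, while another list of that kind, coagulation and complement factors, was lower (percentile 1.74). Hepatocyte plasma proteins (median -0.01, percentile 30.20), hepatocyte transcription factors (0.01, 30.16), acute phase genes (-0.03, 12.79), urea cycle and amino acid catabolism (0.09, 96.69) and fetal liver and liver cancer markers (-0.005, 31.55) stayed within the range of random lists. With only the 7 acute phase genes that share at most 10% of their 32-mers the median was -0.13 (percentile 1.62), and the urea cycle list stood apart with a pseudocount of 5 (percentile 99.06) and without a filter (98.14). ALB (4012 against 4091), AFP (1062 against 1145), HNF4A (79.3 against 81.2) and GAPDH (3069 against 3154) lay within 1.1-fold, and ACTB had a fold of 0.938 (0.924 to 0.953). IGF2, which shares 62.2% of its 32-mers with another gene, was at 295 and 209 (fold 0.71, 0.695 to 0.724), and SPP1, a secreted matrix protein, at 211 and 339 (fold 1.61, 1.56 to 1.67).

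Stress and growth lists other than those above also stayed within the range of random lists. The medians were 0.02 for antioxidant enzymes (percentile 58.56), 0.02 for the unfolded protein response (57.97), 0.02 for the ATF4 response (51.21), 0.09 for heat shock chaperones (97.33), 0.09 for p53 targets (96.47), -0.03 for immediate early genes (10.03), 0.06 for mitosis (87.22) and 0.04 for MYC and ribosome biogenesis (65.14). DDIT3 in the ATF4 list was at 17.8 and 25.8 (fold 1.45, 1.25 to 1.69). Signalling lists gave medians of 0.03 for Wnt targets (58.95), -0.003 for TGFβ and YAP targets (28.26), 0.02 for epithelial junctions (49.60), 0.02 for mesenchymal genes (44.20), 0.01 for NFκB (36.12), 0.05 for interferon (76.97), 0.01 for insulin and growth factors (37.02) and 0.09 for solute carriers (94.48). Nuclear-encoded oxidative phosphorylation had a median of 0.01 (42.07), mitochondrially encoded genes -0.02 (35.29), spliceosome genes 0.02 (51.85) and reference genes -0.02 (23.86). With a pseudocount of 5 heat shock chaperones and solute carriers stood apart (percentiles 98.85 and 98.74). A list of histone genes gave 0.06 over 6 genes (71.67). It was meant for histones without poly(A) tails, but its most abundant member, H1F0 (257 against 220), is a polyadenylated linker histone.

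The 14 nuclear and small non-coding RNAs measured gave that median of -0.18 with 2 members at least 1.5-fold lower. These were SNHG6 at RPKM 85.9 and 51.7 (fold 0.602, 0.526 to 0.688) and SCARNA2. The smallest whole reads of SCARNA2 were 6 in the control and 2 in the DEHP library, and its true reads may be multiples of these. The list's median was -0.12 over 9 features (percentile 1.29) with a mean RPKM of at least 5. With each library rescaled to a common sum it was -0.11 (percentile 0.68). SNHG6 hosts a snoRNA, as do SNHG5 (fold 0.758, 0.692 to 0.83) and GAS5 (0.849, 0.772 to 0.934). The nuclear RNAs MALAT1 and NEAT1 had folds of 1.19 (1.07 to 1.31) and 0.934 (0.87 to 1), and RN7SL1 was at 13.9 and 19.2 (fold 1.38, 0.982 to 1.96). Markers of other cell types were few. The 8 measured genes of the leukocyte and macrophage list, which include hemoglobin genes such as HBA1, had a median of 0.15 (percentile 95.47). Among them the smallest whole reads of FCER1G (fold 3.53, 1.37 to 10.7) were 6 in the control and 20 in the DEHP library. Those of CD3D (0.353, 0.0348 to 1.97) were 6 and 2. The 3 stellate (median -0.04), 1 endothelial (-0.14), 2 other epithelial (-0.13) and 3 neuronal genes (-0.06) were too few for a percentile.

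The most different features with a mean RPKM of at least 5 were mostly copies of other genes, pseudogenes and small RNAs. SULT1A3, a sulfotransferase, was at RPKM 2.81 and 28.1 (fold 10, 7.64 to 13.3), but its identical copy SULT1A4 had a fold of 0.967 (0.86 to 1.09) and the pair summed to 31.8 and 56.2. WASH4P, the read-through gene SLX1A-SULT1A3, MIR1244-2, MIR3189, LOC653375, SNORD36C, RNA5-8SP6, RPS3AP25, MIR4523, LOC402175, SNORA64, AKR1B10 and MIR3687 made up the rest of the 14 highest. The 14 lowest were LOC729217 (44.8 against 1.42, fold 0.0316, 0.00375 to 0.119), the ribosomal pseudogenes RPS28P4, RPS27P19, RPL21P93, RPS26P6, RPS25P2, RPSAP14, RPL35P5, RPL9P9 and RPL34P34, and SNORD84, SNORD57, MIR103A2 and MIR663A. MIR103A2, MIR663A, SNORD57 and SNORD84 have intervals that reach 1, as have WASH4P, MIR3189, SNORD36C, MIR4523 and MIR3687. These intervals rest on the smallest whole reads. Some recovered gene models are very short (45 nt for WASH4P, 39 nt for SNORD84, 18 nt for SNORD57). Where the true reads are multiples, the intervals are too wide, so reaching 1 does not show that a difference is counting error. Of 163 snoRNA features, 33 were at least 2-fold higher and 16 lower, but the median of their smallest whole reads was 4 in the control library. The protein-coding genes at least 2-fold higher were SULT1A3, GSTA2, AKR1B10, S100A9 and FCER1G, and those as much lower were DDTL, GGTLC1, CPA1 and BOLA2B. Those outside the rule for named genes were chosen after their values were seen: S100A9 (fold 3.53, 1.37 to 10.7, from smallest whole reads of 6 and 20), DDTL (0.0515, 0.0203 to 0.109), GGTLC1 (0.202, 0.0503 to 0.598), CPA1 (0.265, 0.136 to 0.482, from smallest whole reads of 56 and 14) and BOLA2B (0.474, 0.411 to 0.545). SULT1A3 and BOLA2B are copied elsewhere in the genome and their folds are uncertain (BOLA2 and BOLA2B summed to 47 and 23.4). Only S100A9 and CPA1 were found to share at most 10% of their 32-mers with another gene. The folds of DDTL and GGTLC1, which did not pass that limit, are therefore uncertain as well.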

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

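The restrictions to protein-coding genes and to unshared sequence were added after seeing the data. The counts of features at least 2-fold higher and lower (86 and 92) depended on how low features were treated: 151 and 180 with a pseudocount of 0.1, 7 and 16 with a pseudocount of 5, 17 and 27 with a mean RPKM of at least 5. They were 177 and 193 with each library rescaled to a common sum as in TPM, which raises every value and so weakens the filter and pseudocount by construction. At 3-fold the counts were 40 and 29, among protein-coding genes 5 and 4, and among protein-coding genes sharing at most 10% of their 32-mers 1 (S100A9) and 1 (CPA1). Without a filter 4 chromosomes (1, 2, 11 and 19) in place of 2 stood apart, and the cause was not tested. The number of lists that stood apart was 10 as reported, 10 to 12 under the alternatives chosen before the data were examined and 8 among unshared members. The median of all features was 0.01 to 0.05 under the alternatives other than centring. Of the values for single genes 2046 moved by less than their counting error and 41 by more, and of list medians 556 moved by less than the spread of random lists and 6 by more. The tally of list medians includes settings that cannot move a median, namely the matching and the fold threshold, so it overstates stability. A filter likewise cannot move a single gene's ratio. Glycolysis became a lower list under 6 alternatives, for instance with matching in 5 bins (percentile 0.98). Xenobiotic metabolism (98.38 with a mean RPKM of at least 5), heat shock chaperones (98.85), urea cycle (99.06) and solute carriers (98.74, these 3 with a pseudocount of 5) became higher, and acute phase genes lower (1.62) among unshared members. Protein-coding genes alone left too few non-coding RNAs for a percentile. The comparison of recovered reads has no alternative, since the planned one applied only if reads could not be recovered.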

Other observations

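The tests of family sums, of counting noise and of 5' TOP mRNAs were chosen or restated after the results were seen. The first bound for counting noise, on the simulated median, had decided neither way, and a test of the scaling was dropped, because 1 factor for all genes cannot set a list apart. Among protein-coding genes with at most 10% of shared 32-mers and a mean RPKM of at least 5, the largest differences, taken after the values were seen, included genes outside the fixed lists. AKR1E2, another aldo-keto reductase, was at RPKM 3.47 in the control and 6.78 in the DEHP library (fold 1.95, 1.5 to 2.56), and SLC6A12, a betaine and GABA transporter, at 5.84 and 10.2 (fold 1.75, 1.43 to 2.15). The lowest log2 ratio among them was that of C9orf116 (8.42 against 3.72, fold 0.442, 0.295 to 0.652). Also lower were HEY1, a Notch target (13.1 against 6.91, fold 0.527, 0.447 to 0.62), LCN15 (48 against 27.4), NDUFA3, a subunit of respiratory complex I (76.6 against 44.8), and TNNI2 (71.3 against 42.6). Of these 5654 genes 8 were at least 1.5-fold higher and 15 lower. Median log2 ratios of 23 chromosomes spanned -0.003 for chromosome 19 (797 genes, percentile 0.00) to 0.05 for chromosome 2 (803 genes, percentile 99.98), and only these 2 stood apart. Under the 7 alternatives run for chromosomes (both rescalings, centring, a mean RPKM of at least 5, no filter and pseudocounts of 0.1 and 5) the median of chromosome 19 was -0.028 to 0.022 and that of chromosome 2 was 0.022 to 0.073, and both stood apart in these 7. Alternatives used 2000 random lists per chromosome.

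Ribosomal protein genes were lower in the DEHP library. Matching random lists on coding length (percentile 0.00) or on GC content (percentile 0.00) left the list outside their range. Coding length and GC content therefore each did not account for the list's median in this matching, which used fewer bins of mean RPKM than the main lists. Transcript length was not matched, so a loss of short, very abundant mRNAs was not excluded. Summing the RPKM of each gene with its own pseudogenes left a median of -0.205. Reads moved between features of unlike length need not leave such sums level, and any reads dropped for matching several places are not counted. The pseudogenes summed were lower too (log2 ratio -0.221). The 51 members that share more sequence had a median of -0.222, against -0.140 for the 5 with little shared sequence. A part played by reads shared with pseudogenes stays open. A hypothesis is a lower level of 5' TOP mRNAs, the class whose translation follows growth signals. The median of 28 such mRNAs outside the ribosomal list lay at percentile 0.95. A narrower set of 22, without members of the fixed lists and without mRNAs for ribosomal proteins, lay at percentile 2.98, so this stays open, as does a difference between the cultures unrelated to DEHP.

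Metallothionein and NRF2 list genes were higher in the DEHP library. In the same matching, coding length did not account for the median of the metallothionein and zinc transport list (percentile 100 with lists matched on it). The lowest log2 ratio among the summed RPKM of metallothioneins, AKR1C and GSTA genes was 0.578. Reads exchanged between members of unlike length need not leave such sums level, so the sums alone do not exclude an exchange. In the AKR1C family no member was lower (lowest log2 ratio 0.03), as an exchange within it would need. The GSTA genes belong to neither list, and AKR1B10 belongs to no summed family. A response of the cells to DEHP is a candidate explanation, and with 1 culture per condition it cannot be separated from other differences in culture, such as the metal content of the medium or serum, which was not tested.

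Of protein-coding genes with a mean RPKM of at least 1, 102 were at least 1.5-fold apart, while 20 simulated pairs with counting error alone gave a median of 29 and at most 41. Counting noise alone falls short of that number, though it may give part of it. With a mean RPKM of at least 5, 3.92% of the genes sharing at least 50% of their 32-mers (16 of 408) were that far apart, against 0.407% (23 of 5654) of those sharing at most 10%. Division of reads between copies is a likely source of some large folds, such as those of the near-identical EIF3C and EIF3CL, whose log2 ratios were -0.93 and 0.93 while their sum was 227 and 251. No biological explanation was tested for this pattern.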
